A study of Mus musculus with 10 samples.

How the data were processed

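Liver RNA of female BALB/cByJ mice, 3 months old, was measured on 10 Affymetrix Mouse Gene 2.1 ST arrays, a platform whose probes lie along the exons of each transcript. The samples came from Pml wild type and Pml knockout mice that were fed ad libitum or had food removed for 6 h. The submitters' note on food removal stands with all 10 samples, the fed ones too, so feeding was taken from sample titles and characteristics. The animals were kept under specific pathogen free conditions with a light and dark cycle. The liver was stored in RNAlater and total RNA was extracted with a miRNeasy kit. The table deposited by the authors holds 1 normalized intensity per probe set and array, on a linear scale. The submitters' processing notes name RMA in Affymetrix Expression Console; versions, library files and genome build are not given in the sources used here. Between 228 and 489 values per array lay under 0.1, which RMA rarely gives, so the exact summary method is open. The log2 of each deposited intensity was taken, with no further normalization.

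The table has 41345 probe sets. The platform table names 25335 of them, 23521 with 1 gene symbol and 1814 with several, and leaves 16010 unnamed. Probe sets with 1 symbol stood for 22180 genes, and no symbol needed an update; 23328 of these probe sets belonged to genes of a RefSeq table (assembly GRCm38.p6), which served for names and for the order of genes along chromosomes. No coordinates are printed, since the build of the array files is unknown. A probe set was kept when it lay above the median (50th percentile) of the array on at least 2 arrays, and the brightest kept probe set stood for its gene. That left 14617 probe sets and 13942 genes, of which 519 had more than 1 kept probe set. Copies within gene families (Hspa1a and Hspa1b, Apol9, Cyp2b, Cyp4a, Acot and Hsd3b genes) may share probes, so a value of such a gene can hold signal of its relatives.

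A linear model with 4 group means was fitted to all 10 arrays in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation (prior degrees of freedom 3.63, residual degrees of freedom 6). There were 7 contrasts: fasting in each genotype, knockout against wild type in each feeding state, the genotype by fasting interaction, and each factor averaged over the other. P values were adjusted by Benjamini-Hochberg over the genes of a contrast, and a gene was called at an adjusted p under 0.05. No batch or pairing is given, so none was modelled. Whether each array is a separate animal is not given either: the p values measure the spread between these samples, part of which can be technical. The number of arrays, 2 per fed group and 3 per fasted group, limits the precision. The Pml level was also compared between 5 and 5 arrays with a two-sided exact permutation test.

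Gene lists, groups, contrasts, tests and the rule for naming genes were fixed before the data were examined. Of 30 lists with 768 entries, 605 entries were tested, and 26 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it, adjusted over the lists of each contrast. The lists cover fatty acid oxidation and ketogenesis, gluconeogenesis and amino acid catabolism, lipogenesis and glycolysis, cholesterol synthesis, p53 targets, NRF2 targets, antioxidant enzymes, oxidative phosphorylation and interferon-stimulated genes. They also cover the circadian clock, endoplasmic reticulum stress, heat shock, bile acids, drug metabolism, the cell cycle, autophagy and lysosome, the acute phase response, immediate early genes, and pericentral and periportal hepatocytes. The others hold markers of macrophages, sinusoidal endothelial cells, stellate cells, cholangiocytes, T and NK cells, and adipocytes. Marker lists of B and plasma cells (4 tested members), neutrophils (4), red blood cells (2) and pancreas (4) fell short of 5 and were not tested.

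The naming rule took Pml, and in each contrast up to 10 higher and 10 lower genes with the largest fold among called genes whose arrays did not overlap between the groups. Predicted, numbered, microRNA, small nucleolar, olfactory, vomeronasal and pseudogene symbols were counted and not named. It also took up to 4 members of each list with the smallest p. For the interaction, no overlap means that no difference between a fasted and a fed knockout array lay within the range of such differences in wild type. For the averaged contrasts, it means separation in the same direction within each stratum.

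Alternatives were centring of each array, repeated quantile normalization, no filter and a stricter filter (70th percentile), the mean of all probe sets of a gene, and moderation with trend and robust. Further ones were array weights, the replicate number as a block, a fit of the groups of 1 contrast alone, the other list tests, and the omission of each array in turn. Chosen after the data were seen were a clock score as a covariate (the mean of 5 clock genes minus the mean of 7 others), and the omission of fasted knockout replicates 1 and 2. So were fits with 1 fasted knockout array, an offset of 16 with no filter, and a block with exchanged numbers in fed knockout. Where an omission leaves 1 array in a group, that array is assumed to vary like the other groups. In simulated data on the 13942 genes, 200 of them changed, the fit recovered for the fasted knockout against wild type comparison 44.6% of genes changed 1.5-fold, 79.6% of those changed 2-fold and 97.0% of those changed 4-fold. For the interaction it recovered 4.78%, 43.9% and 87.7%, and for the fed comparison of genotypes 25.2%, 68.1% and 95.0%. The simulated noise was drawn independently per gene, with the same spread in each group. These rates therefore do not model correlated genes or a split among the arrays of a group.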

Results

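Transcript levels were measured in 10 liver samples of Pml wild type and Pml knockout mice. The question was how loss of Pml, the gene of the protein that organises PML nuclear bodies, changes liver gene expression in the fed state and after a short fast. The groups were wild type fed ad libitum (2 arrays), knockout fed ad libitum (2), wild type with food removed for 6 h (3) and knockout with food removed for 6 h (3). Array medians lay between 43.5 and 47.5 intensity units. Changes are given as log2 differences with the standard error (SE) of the fit, and p values are adjusted over the 13942 genes tested. The array median serves as a floor. Where every array of a group lay at or below it, the change is given as at least the fold of the brighter group against that median.

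Pml itself, measured by 1 probe set, was lower in knockout in both feeding states. Its log2 intensity was 8.29 ± 0.11 (SD, n = 2) in fed wild type and 6.66 ± 0.36 (SD, n = 2) in fed knockout. After fasting it was 7.78 ± 0.32 (SD, n = 3) in fasted wild type and 6.18 ± 0.15 (SD, n = 3) in fasted knockout. The averaged difference was -1.62 (SE 0.14, adjusted p = 0.0103), which leaves 32.6% of the wild type level. The probe set may lie in part outside the deleted sequence, which is not given in the sources used here. Wild type arrays lay between 7.50 and 8.37 and knockout arrays between 6.05 and 6.91. An exact permutation test, two-sided over 252 divisions, gave p = 0.00794, the smallest it can give. The averaged limma call was lost without fed knockout replicate 2 (-1.49, adjusted p = 0.0645), or without fasted wild type replicate 1 (-1.63, adjusted p = 0.0581). It was also lost with the clock score as a covariate (-1.63, adjusted p = 0.169) and without fasted knockout replicates 1 and 2 (-1.64, adjusted p = 0.173). Over 21 alternatives the adjusted p lay between 0.000619 and 0.173.

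Genes of the circadian clock separated the fasted knockout arrays from one another, and also separated fed from fasted wild type. These genes were chosen for per-array values after they had been seen. Arntl, the clock transcription factor BMAL1, had a log2 intensity of 9.16 ± 0.13 (SD, n = 3) in fasted wild type, against 4.60, 4.53 and 8.87 in fasted knockout replicates 1, 2 and 3. Dbp, a clock output gene, was 6.43 ± 0.31 (SD, n = 3) in fasted wild type and 10.05, 9.80 and 6.00 in those 3 arrays. The fed means were 9.54 in wild type and 9.95 in knockout. Cdkn1a, the cell cycle inhibitor p21, followed the same division, with 11.32 ± 0.06 (SD, n = 3) in fasted wild type, 5.26, 6.27 and 10.84 in fasted knockout and fed means of 5.29 and 5.35. The clock score was -0.67 and -1.08 in fed wild type, -1.84 and -1.78 in fed knockout, between 2.19 and 2.81 in fasted wild type, and -2.36, -2.08 and 2.39 in fasted knockout replicates 1, 2 and 3.

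**Figure D1:**
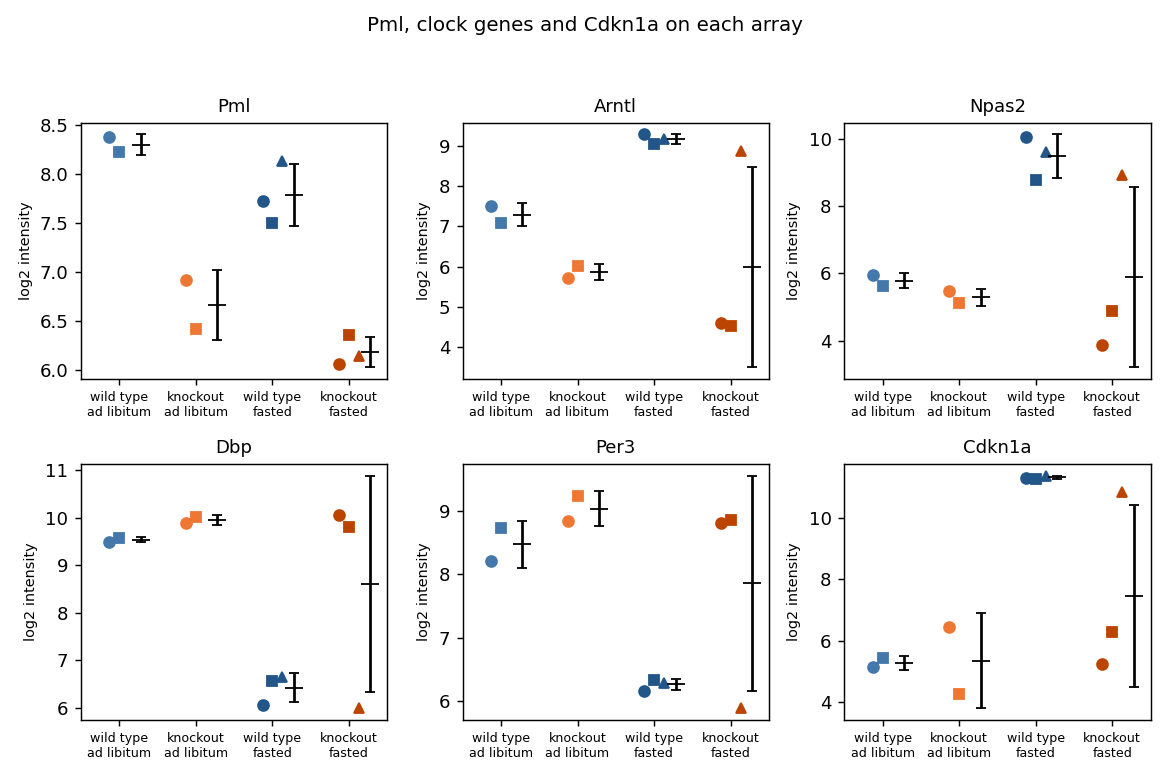
Log2 intensity of Pml, Arntl, Npas2, Dbp, Per3 and Cdkn1a on each array, by group (circle, replicate 1; square, replicate 2; triangle, replicate 3; bar, mean ± SD). Fasted knockout replicate 3 (Arntl 8.87) lies near fasted wild type and replicates 1 and 2 (4.60 and 4.53) far from it, while Pml is low in each knockout array.

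The first comparison asked what 6 h without food changed in wild type liver. Cidec, a lipid droplet protein, rose 57.4-fold (log2 5.84, SE 0.44, adjusted p = 0.000218). Pdk4, the kinase that restrains pyruvate dehydrogenase, rose 27.5-fold (log2 4.78, SE 0.68, adjusted p = 0.00168). Igfbp1, an insulin-repressed secreted protein, rose 27.4-fold (log2 4.78, SE 0.37, adjusted p = 0.000218). Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, rose 62.3-fold (log2 5.96, SE 0.53), and Cdkn1a rose at least 57.1-fold (adjusted p = 0.0116). Acot1 (4.68), Plin4 (4.47), Acot2 (4.20), the stress gene Gadd45b (4.72) and the metallothionein Mt1 (4.15) followed. Lower were Hsd3b5, a male-biased steroid enzyme (25-fold, log2 -4.64, SE 0.72), the retinoic acid hydroxylase Cyp26a1 (at least 3.53-fold) and the lipogenesis gene Mid1ip1 (at least 5.60-fold). The pericentral receptor Lgr5 (at least 4.68-fold), Cyp2g1 (-2.99) and the clock genes Nr1d1 (-3.12) and Dbp (-3.11) fell too. Plin4 lay above the array median on 1 of 2 fed arrays. In all 2990 genes were called, 1147 higher and 1843 lower (n = 2 fed and 3 fasted). Of these 2989 had arrays that did not overlap, as did 52.7% of all genes, where chance gives 20%.

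By gene list, fatty acid oxidation and ketogenesis rose, with 29 of 36 members higher, 0 lower and 7 not called (32 higher and 1 lower adjusted over the list alone; median log2 0.79, camera adjusted p = 2.35e-19). Its members Fgf21 (3.61), Slc22a5 (2.44) and Pex11a (2.26) were among them; Fgf21 lay above the array median on 1 of 2 fed arrays. Cholesterol synthesis fell, with 16 of 20 members lower (17 adjusted over the list alone; median -1.70, adjusted p = 4.98e-12), such as Mvk (-2.92), Cyp51 (-2.58) and Sqle (-2.51); Mvk lay above the array median on 1 of 3 fasted arrays. Lipogenesis and glycolysis fell, with 11 of 25 lower and 2 higher (15 and 3 adjusted over the list alone; median -0.72, adjusted p = 0.00385), led by Srebf1 (-2.80), the master regulator of lipogenesis, and Acly (-2.26). Immediate early genes rose, with 14 of 17 higher (15 adjusted over the list alone; median 1.19, adjusted p = 4.75e-10), such as Jun (3.30) and Egr1 (2.43). Interferon-stimulated genes fell, with 19 of 39 lower (19 adjusted over the list alone; median -0.72, adjusted p = 1.98e-05), such as Gbp7 (-1.69), Isg15 (at least 1.59-fold) and Irf1 (-1.40). The cell cycle list fell, with 7 of 21 lower (10 adjusted over the list alone; median -0.58, adjusted p = 0.00177). Gluconeogenesis and amino acid catabolism was called upward (10 of 28 higher and 2 lower, median 0.20, adjusted p = 0.00871). So were heat shock (3 of 15 higher, median 0.19, adjusted p = 0.0295) and drug metabolism (5 of 23 higher, median 0.12, adjusted p = 0.0205). The acute phase list was also called upward (9 of 28 higher, adjusted p = 0.0205), with a median of -0.03 and a mean of 0.52, so that its median and its test differ in sign. Of p53 targets 7 of 26 rose and 3 fell, and the list was not called (adjusted p = 0.149). With an estimated correlation the call of the immediate early genes held (adjusted p = 0.0105). The other 9 calls were lost, with adjusted p = 0.206 for fatty acid oxidation, 0.213 for cholesterol synthesis, 0.692 for heat shock and 0.595 for the remaining 6. Fry called 12 lists.

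Clock scores of fed and fasted wild type arrays did not overlap, as given above. The time of collection is not given, so food removal and clock state cannot be told apart in this comparison. Without fed wild type replicate 1 the count was 1326, without replicate 2 it was 1941, and with the clock score as a covariate 929. The call of Cdkn1a was lost without fed wild type replicate 1 (adjusted p = 0.0718). The heat shock list was lost without the same array (adjusted p = 0.510) or fasted wild type replicate 3 (0.111). The call of gluconeogenesis was lost without fed wild type replicate 2 (adjusted p = 0.0698) and that of the acute phase list without that array (0.111) or fasted wild type replicate 1 (0.0593). The mean of drug metabolism went from 0.48 to 0.20 without fed wild type replicate 1 (adjusted p = 0.0499) and to 0.77 without replicate 2. That of heat shock went from 0.28 to 0.51 without replicate 2. Dbp was lost without any 1 of the fed arrays or the fasted wild type arrays (adjusted p between 0.0634 and 0.159). Centring each array moved the median of all genes from -0.02 to 0.08 and turned the balance of directions, to 1762 higher and 1296 lower.

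In Pml knockout liver the fast raised Cidec 8.48-fold (log2 3.08, SE 0.44, adjusted p = 0.0278), Mt1 6.60-fold (log2 2.72, SE 0.32, adjusted p = 0.0145) and Gadd45b 5.60-fold (log2 2.49, SE 0.42, adjusted p = 0.0323). The inflammatory cytokine gene Il1b rose at least 1.99-fold (adjusted p = 0.00797), and Myc (1.69), Jun (1.60) and Acot2 (1.69) were also higher. Lower were Pdgfrl (5.18-fold, log2 -2.37, SE 0.35; above the array median on 1 of 3 fasted arrays), Srebf1 (4.32-fold, log2 -2.11, SE 0.39) and Fasn, the fatty acid synthase (-1.83, SE 0.31). So were the endoplasmic reticulum chaperone genes Sdf2l1 (-1.99) and Hyou1 (-1.72), and the transcriptional repressor Bcl6 (-1.60, SE 0.16). The test called 234 genes, 113 higher and 121 lower (n = 2 fed and 3 fasted). Over the 10 omissions of 1 array most of these calls were lost at least once. That of Cidec was lost in 4 (adjusted p between 0.0529 and 0.184), Gadd45b in 6 (0.0519 to 0.194), Mt1 in 2 (0.0563 and 0.0870) and Il1b in 1 (0.0753). Myc lost it in 7 (0.0519 to 0.117), Jun in 6 (0.0511 to 0.143), Acot2 in 9 (0.0645 to 0.282) and Pdgfrl in 3 (0.0643 to 0.192). Srebf1 lost it in 7 (0.0588 to 0.259), Fasn in 5 (0.0519 to 0.194), Sdf2l1 in 3 (0.0563 to 0.143) and Hyou1 in 5 (0.0519 to 0.193). The arrays of these 234 did not overlap, as was true of 36.8% of all genes, where chance gives 20%.

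Fatty acid oxidation rose, with 2 of 36 members called (16 adjusted over the list alone; median 0.35, adjusted p = 6.07e-08). Immediate early genes rose, with 5 of 17 called (6 adjusted over the list alone; median 0.42, adjusted p = 2.45e-05). Lipogenesis and glycolysis fell, with 4 of 25 lower (9 adjusted over the list alone; median -0.66, adjusted p = 1.25e-08). Cholesterol synthesis fell as a list (median -0.65, adjusted p = 1.33e-07), with 0 of 20 members called over all genes by limma and 11 lower adjusted over the list alone. Endoplasmic reticulum stress genes fell, with 6 of 25 lower (15 lower and 3 higher adjusted over the list alone; median -0.44, adjusted p = 3.42e-06). Periportal genes (2 of 17 lower, median -0.22, adjusted p = 0.00150) and sinusoidal endothelial markers (0 of 18 called, median -0.16, adjusted p = 0.0229) fell as lists. The acute phase list rose (0 of 28 called, median 0.12, adjusted p = 0.00334). Interferon-stimulated genes were not called (median 0.19, adjusted p = 0.140). The 8 calls were lost with an estimated correlation, with adjusted p = 0.0683 for immediate early genes and between 0.428 and 0.734 for the others. Fry called 7 lists. The fasted knockout arrays split by clock genes as given above, and the gene count moved with single arrays. It was 24 without fed knockout replicate 1 and 1 without replicate 2. It was 142, 62 and 10 without fasted knockout replicates 1, 2 and 3, and 137, 42 and 33 without fasted wild type replicates 1, 2 and 3. It was 10 with no filter, 452 with a stricter filter, and 504 with trend and robust moderation. Fitting the knockout groups alone gave 16, the clock covariate 27 and the replicate block 0, where limma gave 2310 genes at an unadjusted p under 0.05. The sinusoidal endothelial call was lost without fed knockout replicate 1 (adjusted p = 0.0586) or fasted knockout replicate 1 (0.153).

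Set side by side, the fasting responses of the genotypes ran mostly in the same direction. Across genes, which are not independent replicates, the fold changes correlated with Pearson r = 0.47 and Spearman rho = 0.37, and the slope of knockout on wild type was 0.31 over the 3073 genes called in either genotype. Of the 2990 genes called in wild type, 2312 (77.3%) had the same sign in knockout, with a median ratio of knockout to wild type of 0.27. Of the 706 that changed at least 2-fold in wild type, 688 (97.5%) changed less in knockout than in wild type. The slope, the ratio and these shares rest mostly on genes chosen by their wild type response, which by itself favours a smaller knockout value. Of the 234 genes called in knockout, a choice that favours the opposite, 86 (36.8%) changed less in knockout than in wild type. These values therefore do not settle which response was larger; the interaction below tests the difference per gene. Both genotypes shared 151 calls, 147 in the same direction, where chance gives 50.2. With no filter on dim probe sets the Pearson correlation was 0.22.

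Between fed knockout and fed wild type few genes differed. Clock scores of these groups did not overlap, as given above, while the clock list was not called (camera adjusted p = 0.114). Genotype and clock state therefore cannot be told apart in this comparison either. Ppp1r3g was 59.1-fold higher in knockout (log2 5.88, SE 0.58, adjusted p = 0.0256), at 12.07 ± 1.07 (SD, n = 2) against 6.19 ± 0.32 (SD, n = 2). That is close to its fasted levels of 12.15 in wild type and 12.22 in knockout. Txnip, a glucose-responsive thioredoxin-binding protein, was higher (1.47, SE 0.20), as was Cyp2b10, a target of the nuclear receptor CAR (0.89, SE 0.12). Also higher were Cpsf4l (1.59, SE 0.20) and Zbtb16 (1.53, SE 0.21), which lies within 20 Mb of Pml. Lower were Pinx1 (-1.40, SE 0.19), Snx11 (-0.79, SE 0.10) and Pml itself (-1.63, SE 0.22). Each of these genes but Ppp1r3g had an adjusted p of 0.0398. Of 10 omissions of 1 array, the call was lost in 6 for Ppp1r3g and 8 for Txnip and Cpsf4l. It was lost in 9 for Cyp2b10, Pinx1 and Snx11 and in 10 for Zbtb16 and Pml. The test called 12 genes, 8 higher and 4 lower (n = 2 per group), without overlap between arrays. Chance gives no overlap for 33.3% of genes, and 39.9% of all genes showed it. Centring each array left 8 higher and 1 lower.

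The cholesterol synthesis list was lower in fed knockout, with 0 of 20 members called over all genes by limma and 14 lower adjusted over the list alone (median -0.69, adjusted p = 6.10e-14). Its members Cyp51 (-1.34), Hmgcs1 (-1.19) and Mvk (-1.13) were among those 14. Fatty acid oxidation was higher as a list (0 of 36 called, 1 adjusted over the list alone; median 0.26, adjusted p = 2.95e-12). Drug metabolism was higher too, with Cyp2b10 alone of 23 members called (2 adjusted over the list alone; median 0.16, adjusted p = 1.06e-05). Gluconeogenesis (median 0.06, adjusted p = 0.00259) and sinusoidal endothelial markers (median 0.10, adjusted p = 0.00926) were called higher. The cell cycle list was called lower (median -0.35, adjusted p = 0.000631). Each of these 3 lists had 0 members called over all genes. The 6 calls were lost with an estimated correlation, with adjusted p between 0.348 and 0.784, and fry called 0. Drug metabolism rests on fed wild type replicate 1: its mean was 0.39 with all arrays, 0.10 without that array (adjusted p = 0.00302) and 0.67 without replicate 2. Without fed wild type replicate 2 gluconeogenesis (adjusted p = 0.174) and the endothelial markers (0.430, mean from 0.10 to 0.05) were lost. The gene count was 0 by limma without fed knockout replicate 2, fasted wild type replicate 1 or 3, or fasted knockout replicate 1 or 2 (992 to 1254 genes at an unadjusted p under 0.05). It was 3 without fed wild type replicate 2, 7 without fed knockout replicate 1 and 2 without fasted wild type replicate 2. It was 4 with no filter, 24 with trend and robust moderation, 1 with the clock covariate and 2 without fasted knockout replicates 1 and 2. It was 0 with the replicate block (1160 at an unadjusted p under 0.05), the block with exchanged numbers (1249) or the fed groups alone (1215).

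**Figure D2:**
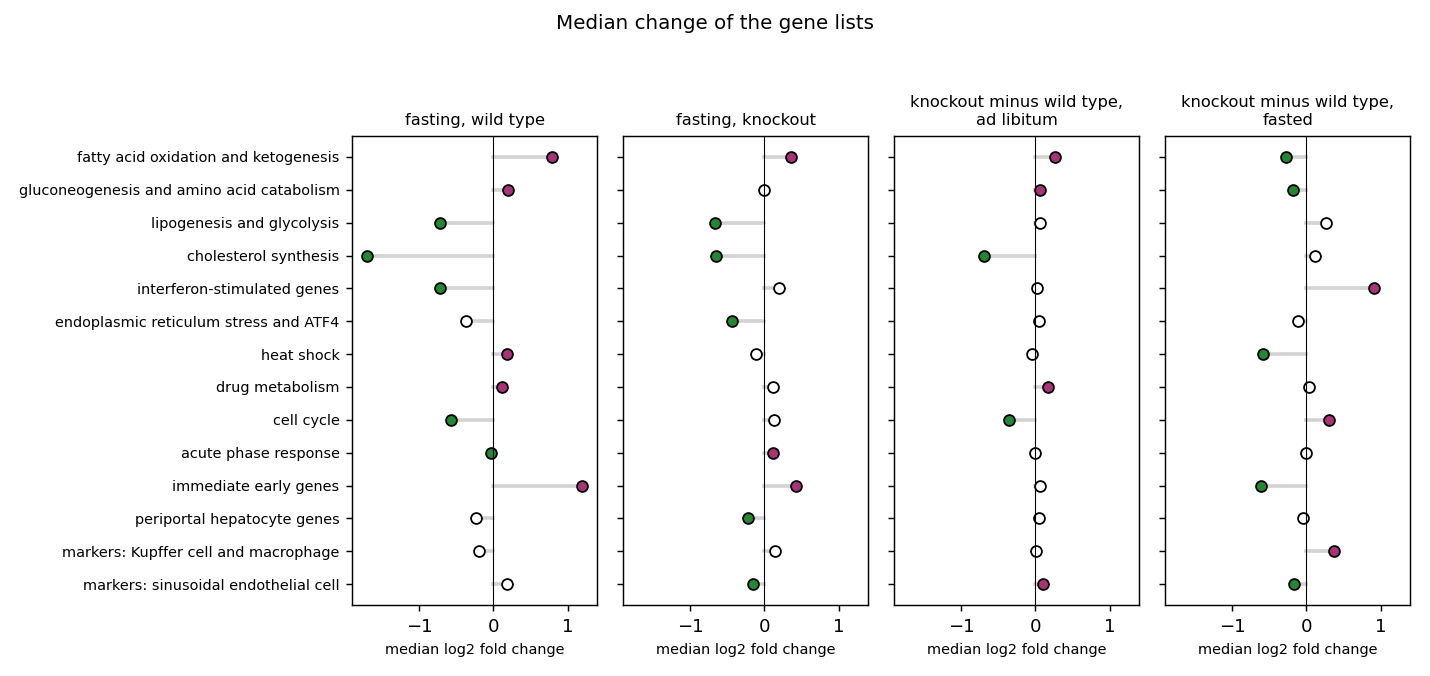
Median log2 difference of the 14 gene lists called in at least 1 of the 4 comparisons between groups, 1 panel per comparison (filled dot, called by camera at the preset correlation; magenta, positive; green, negative). Cholesterol synthesis lies at -1.70 for fasting in wild type and -0.69 in fed knockout against wild type, and interferon-stimulated genes at 0.91 in fasted knockout against wild type.

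After the fast many more genes were called between the genotypes, with 3 arrays per group against 2 in fed mice. The counts alone do not test a difference between the feeding states, which the interaction below does. Higher in fasted knockout were Cyp2g1 (7.99-fold, log2 3.00, SE 0.32, adjusted p = 0.00422) and Lgr5 (at least 3.40-fold, adjusted p = 0.00489). So were the interferon-inducible GTPase Gbp10 (5.45-fold, log2 2.45, SE 0.31, adjusted p = 0.00489) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (4.39-fold, log2 2.13, SE 0.25, adjusted p = 0.00433). Mmd2 (2.09), Hsd3b2 (2.29) and the interferon-inducible Apol9a (2.00, SE 0.20) were also higher. Lower were Pdk4 (9.12-fold, log2 -3.19, SE 0.61, adjusted p = 0.0137), Cidec (6.46-fold, log2 -2.69, SE 0.39, adjusted p = 0.00685) and the heat shock gene Hspa1b (4.96-fold, log2 -2.31, SE 0.27, adjusted p = 0.00433). Hspa1b lay above the array median on 1 of 3 fasted knockout arrays. The near-identical copy Hspa1a read -0.26 and was not called. Lower too were Plin4 (-2.24), Acot2 (-2.10) and the clock gene Cry1 (-2.17). The test called 1549 genes, 931 higher and 618 lower (n = 3 per group). Of these 1548 had arrays that did not overlap, as did 33.0% of all genes, where chance gives 10%. Cdkn1a (-3.87, SE 1.18, adjusted p = 0.0638), Arntl (-3.16, SE 0.93, adjusted p = 0.0577) and Npas2 (-3.58, adjusted p = 0.0533) were not called, given the split among the fasted knockout arrays. Arntl and Npas2 lay below the array median in fasted knockout replicates 1 and 2, and Cdkn1a in replicate 1, so these sizes are not exact.

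Interferon-stimulated genes were higher, with 20 of 39 members called higher and 0 lower (27 adjusted over the list alone; median 0.91, adjusted p = 5.57e-12), such as Isg15 (at least 2.15-fold), Psmb9 (1.78), Igtp (1.73) and Ifit1 (1.72). Macrophage markers were higher beside them, with 4 of 18 called (10 adjusted over the list alone; median 0.37, adjusted p = 0.000443): Cd5l (0.65), Adgre1 (0.54), Csf1r (0.38) and Cd68 (0.36). Heat shock genes were lower, with 5 of 15 called (8 adjusted over the list alone; median -0.59, adjusted p = 5.64e-06), among them Hspb1 (-1.39) and Bag3 (-1.06). Immediate early genes were lower, with 7 of 17 called (8 adjusted over the list alone; median -0.61, adjusted p = 2.16e-05), among them Jun (-1.43) and Atf3 (-1.65), which lay above the array median on 1 of 3 fasted knockout arrays. Fatty acid oxidation was lower, with 7 of 36 lower and 1 higher (11 and 1 adjusted over the list alone; median -0.27, adjusted p = 1.10e-05), among them Fgf21 (-1.76) and Ehhadh (-1.08). Gluconeogenesis and amino acid catabolism was lower (6 of 28 lower and 1 higher, median -0.18, adjusted p = 0.0292), with Igfbp1 at -1.36 and Irs2, an insulin receptor substrate, at -1.10. The cell cycle list was higher (5 of 21, median 0.31, adjusted p = 0.0175), with the replication factor Mcm4 at least 2.06-fold higher. Sinusoidal endothelial markers were lower (2 of 18, median -0.17, adjusted p = 0.0103). The p53 target list was not called (2 of 26 higher and 2 lower, adjusted p = 0.292). Its members Dglucy (1.07) and Ccng1 (0.54) were higher, and Tigar (-0.61) and Mdm2, the ubiquitin ligase of p53 (-0.42), were lower. These 8 list calls were lost with an estimated correlation, with adjusted p = 0.0631 for immediate early genes and 0.741 for each of the others. Fry called 2 lists.

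Of the fasted knockout arrays, replicates 1 and 2 had clock gene levels far from fasted wild type. The count was 435 without replicate 1, 1335 without replicate 2 and 1501 without replicate 3, the last 2 sharing 1069 and 1130 genes with the full set. In tests chosen after the split was seen it was 6 without replicates 1 and 2, 1509 with replicate 1 alone, 149 with replicate 2 alone and 34 with the clock covariate. The median of the interferon list was 0.65 without replicate 3, 1.04 without replicates 1 and 2 and 1.07 with the clock covariate, with 16, 1 and 8 members called. That of heat shock was -0.63, -0.58 and -0.63. For fatty acid oxidation it was -0.27, -0.14 and -0.14, and for immediate early genes -0.68, -0.44 and -0.49. The call of Pdk4 was lost without fasted wild type replicate 3 (-3.13, adjusted p = 0.0512). That of Plin4 was lost without fasted wild type replicate 1 (-1.95, adjusted p = 0.0762), 2 (-2.39, 0.0504) or 3 (-2.37, 0.0616) or fasted knockout replicate 1 (-1.88, 0.0946). Further calls lost in some of 10 omissions of 1 array were Cd68 (10, adjusted p between 0.0505 and 0.127), Csf1r (7, 0.0528 to 0.112) and Cd5l (7, 0.0528 to 0.133). So were Igfbp1 (5, 0.0567 to 0.108), Irs2 (5, 0.0647 to 0.122), Mdm2 (5, 0.0707 to 0.117), Hsd3b2 (2, 0.0517 and 0.0613) and Atf3 (2, 0.0638 and 0.0754). The gluconeogenesis list was lost without fasted wild type replicate 1 (adjusted p = 0.111) or 2 (0.107) or fasted knockout replicate 1 (0.176). The cell cycle list was lost without fasted wild type replicate 2 (0.0614) or fasted knockout replicate 2 (0.0647). Without fasted wild type replicate 1, 2 or 3 the count was 724, 743 and 536, with no filter 654, and with the fasted groups fitted alone 850.

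**Figure D3:**
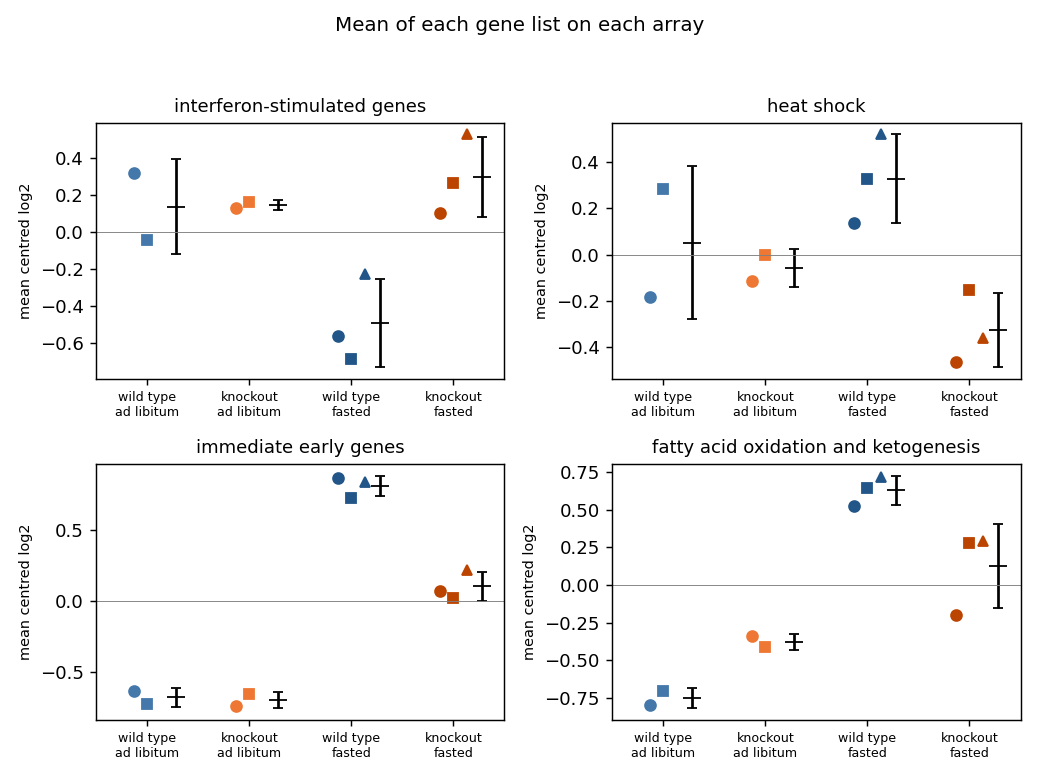
Mean centred log2 intensity of the members of 4 gene lists (interferon-stimulated, heat shock, immediate early, and fatty acid oxidation genes) on each array, by group (circle, replicate 1; square, replicate 2; triangle, replicate 3; bar, mean ± SD). The interferon list lies between -0.69 and -0.23 in fasted wild type and between 0.10 and 0.53 in fasted knockout.

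The interaction tested whether the fast changed a gene differently in knockout and wild type. Cyp7a1 differed most upward (3.57, SE 0.40, adjusted p = 0.0170). It was lower after fasting in wild type (11.56 to 9.41) and higher in knockout (10.13 to 11.55). Lgr5 (3.40, SE 0.55) and Cyp2g1 (3.31, SE 0.50) were lower after fasting in wild type and near the fed level in fasted knockout. Mvk, an enzyme of cholesterol synthesis (2.21, SE 0.25), and the replication genes Mcm4 (2.20, SE 0.31) and Gins1 (2.19, SE 0.38) differed in the same direction. Every fasted wild type array lay at or below the array median for Lgr5, Mcm4 and Gins1, and 2 of 3 did for Mvk, so these sizes are not exact. Every fed knockout array did for Gins1. Downward, Ppp1r3g (-5.82, SE 0.75, adjusted p = 0.0221) was already high in fed knockout. Igfbp1 (-3.25, SE 0.52) differed by 1.53 between fasted and fed knockout, which was not called, against 4.78 in wild type. Pdgfrl (-3.58, SE 0.50), Tacc2 (-2.64, SE 0.23, adjusted p = 0.00743), Acot2 (-2.52, SE 0.49) and Ccn2 (-2.15, SE 0.37) followed, Pdgfrl with 1 of 3 fasted knockout arrays above the array median. The test called 294 genes, 184 upward and 110 downward (n = 2 fed and 3 fasted per genotype). Calls were lost in some of 10 omissions of 1 array: 1 for Cyp7a1 and Ppp1r3g (adjusted p = 0.0735 for both), 2 for Mvk, Mcm4 and Pdgfrl (0.0572 to 0.0844) and 5 for Lgr5 (0.0576 to 0.0844). It was 6 for Cyp2g1 and Igfbp1 (0.0531 to 0.0921), 7 for Gins1 and Acot2 (0.0544 to 0.131) and 8 for Ccn2 (0.0544 to 0.0981). The balance was 93 and 125 after centring each array and 126 and 115 after quantile normalization.

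Cholesterol synthesis differed upward, with 5 of 20 members called (11 adjusted over the list alone, median 0.97, adjusted p = 4.39e-08). So did interferon-stimulated genes, with 4 of 39 called (20 adjusted over the list alone, median 0.85, adjusted p = 3.02e-08), and the cell cycle list, with 2 of 21 (5 adjusted over the list alone, median 0.73, adjusted p = 6.18e-05). For cholesterol synthesis the genotypes differed more in fed mice (median -0.69) than in fasted mice (0.12, not called, camera adjusted p = 0.146). Fatty acid oxidation differed downward, with 5 of 36 called (18 adjusted over the list alone, median -0.49, adjusted p = 1.24e-12). Immediate early genes did too, with 2 of 17 (7 adjusted over the list alone, median -0.52, adjusted p = 0.000113), as did gluconeogenesis, with 3 of 28 (median -0.19, adjusted p = 0.000325). Further lists called downward were heat shock (0 of 15; median -0.44, adjusted p = 0.000325) and sinusoidal endothelial markers (0 of 18; median -0.41, adjusted p = 0.000241). Macrophage markers differed upward (0 of 18; median 0.40, adjusted p = 0.00383). The 9 calls were lost with an estimated correlation, with adjusted p = 0.0986 for immediate early genes, 0.412 for cholesterol synthesis, fatty acid oxidation and the cell cycle, and 0.576 for the others. Fry called 3 lists, and the macrophage call was lost without fed wild type replicate 1 (adjusted p = 0.231; mean from 0.35 to 0.16, and 0.54 without replicate 2). The mean of heat shock went from -0.54 to -0.31 without that replicate 1. The clock genes split the fasted knockout arrays here too. The wild type side of the interaction also holds the clock difference between fed and fasted arrays. The count was 0 by limma without replicates 1 and 2 (2561 at an unadjusted p under 0.05), 52 without replicate 1 and 22 with the clock covariate. It was 13 and 2 without fed knockout replicate 1 and 2, 83 and 120 without fed wild type replicate 1 and 2, and 60, 40 and 56 without fasted wild type replicate 1, 2 and 3. It was 4 with no filter, 501 with a stricter filter, 520 with trend and robust moderation and 137 with the replicate block.

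Averaged over feeding, knockout differed from wild type in 24 genes, 11 higher and 13 lower (n = 5 per genotype). Mmd2 (1.53, SE 0.21), Apol9a (1.19, SE 0.16) and Txnip (0.91, SE 0.13) were higher, as were Bco2 (0.96, SE 0.15) and Colca2 (0.71, SE 0.11), which lie within 20 Mb of Pml. Besides Pml, Bcl6 (-0.95, SE 0.11), Trmt61a (-0.79, SE 0.11) and Tigar, a p53-induced regulator of glycolysis (-0.66, SE 0.08), were lower, with adjusted p between 0.0401 and 0.0481 for these genes. Each of these genes but Pml lost its call in 7 to 9 of 10 omissions of 1 array (adjusted p between 0.0633 and 0.192). In 16 of the 24 genes the arrays separated in the same direction in both feeding states, as in 5.76% of all genes, where chance gives 1.67%. Lists called were interferon-stimulated genes (higher, 0 of 39 members called, 15 adjusted over the list alone, median 0.38, adjusted p = 8.63e-11) and heat shock (lower, 1 of 15, 5 adjusted over the list alone, median -0.29, adjusted p = 3.09e-05). Also called were cholesterol synthesis (lower, median -0.21, adjusted p = 0.00245), drug metabolism (higher, median 0.10, adjusted p = 0.00177), immediate early genes (lower, median -0.29, adjusted p = 0.00362) and macrophage markers (higher, median 0.13, adjusted p = 0.00362). With an estimated correlation the 6 calls were lost, with adjusted p between 0.282 and 0.845, and fry called 1. Each of the 6 lists was called in 1 feeding state alone. The cholesterol list was lower in fed mice (median -0.69); in fasted mice its median was 0.12, with 4 of 20 members higher and no call (adjusted p = 0.146). Drug metabolism was called in fed mice and read 0.03 in fasted mice (adjusted p = 0.678). The others were called in fasted mice, and the fed medians were 0.02 for interferon-stimulated genes (adjusted p = 0.780), -0.05 for heat shock (0.552), 0.07 for immediate early genes (0.509) and 0.00 for macrophage markers (0.989). Without fed wild type replicate 2 cholesterol synthesis (adjusted p = 0.0866) and the macrophage markers (0.429) were lost. Without fed wild type replicate 1 the mean of the macrophage markers went from 0.15 to 0.25. That of drug metabolism went from 0.27 to 0.12 without replicate 1 and to 0.41 without replicate 2. The gene count was 0 by limma without fed knockout replicate 2 (1872 at an unadjusted p under 0.05), fasted wild type replicate 1 (2171) or fasted knockout replicates 1 and 2 together (1594), and with the clock covariate (1242). It was 257 without fasted knockout replicate 3. Fewer genes were called without fed wild type replicate 2 (2), fed knockout replicate 1 (7), fasted wild type replicate 2 (1) or 3 (3), or fasted knockout replicate 1 (4) or 2 (1). It was 3 with no filter, 97 with a stricter filter or with trend and robust moderation, 37 with array weights and 7 with the replicate block.

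Averaged over genotype, fasting raised Cidec (4.46, SE 0.31), Gadd45b (3.60, SE 0.29), Mt1 (3.44, SE 0.22), Igfbp1 (3.16, SE 0.26) and the hepatokine gene Fgf21 (2.39, SE 0.30). It lowered the calcium pump gene Atp2b2 (-2.71, SE 0.47), Mid1ip1 (-2.57, SE 0.34), Srebf1 (-2.46, SE 0.28) and Sdf2l1 (-2.07, SE 0.18). Every fasted array lay at or below the array median for Atp2b2, and every fasted wild type array did for Mid1ip1, so these 2 sizes are not exact. Adjusted p lay between 0.000128 and 0.00409 for these genes. The test called 3017 genes, 1284 higher and 1733 lower (n = 4 fed and 6 fasted), against 1773 and 1296 after centring each array. In 1876 the arrays separated in both genotypes, as in 17.1% of all genes, where chance gives 2%. Of 36 fatty acid oxidation genes 30 rose, and of 17 immediate early genes 13 rose. By contrast 16 of 20 cholesterol synthesis genes, 13 of 25 lipogenesis genes and 14 of 25 endoplasmic reticulum stress genes fell, while 1 lipogenesis and 3 stress genes rose. Camera called 9 lists: these 5, interferon-stimulated genes (8 of 39 lower, median -0.16, adjusted p = 0.0246), drug metabolism (5 of 23 higher), the acute phase response (9 of 28 higher) and periportal genes (8 of 17 lower and 2 higher). The interferon list differed in sign between the genotypes, with a median of -0.72 and 19 of 39 lower in wild type, against 0.19 and no call in knockout (adjusted p = 0.140). With an estimated correlation the immediate early genes held (adjusted p = 0.0114) and the other 8 calls were lost, with adjusted p between 0.219 and 0.818. Fry called 12 lists. The interferon call was lost without fed wild type replicate 1 (adjusted p = 0.176), fasted wild type replicate 2 (0.0744) or fasted knockout replicate 1 (0.0994) or 2 (0.0548). That of drug metabolism was lost without fed knockout replicate 1 (0.0778) or fasted knockout replicate 1 (0.0660) or 2 (0.0601), and that of periportal genes without fed wild type replicate 1 (0.0536). Without that array the mean of drug metabolism went from 0.36 to 0.22. Clock scores were negative in the fed arrays and in fasted knockout replicates 1 and 2, and positive in the other fasted arrays. In wild type, food removal and clock state therefore cannot be told apart here either. The count was 1750 without fed wild type replicate 1, 1925 and 1585 without fed knockout replicate 1 and 2, 1774 with the replicate block and 864 with the clock covariate.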

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

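The tests of the clock genes, of the labels and feeding of the fasted knockout arrays and of the interferon genes were chosen after these results were seen; the splits of the samples and the test of genes near Pml were planned.

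The response to fasting differed between the genotypes in 294 genes by the interaction test. The count was 52 without fasted knockout replicate 1 and 22 with the clock covariate. The upward interaction values of the named genes were Cyp7a1 3.57, Lgr5 3.40, Cyp2g1 3.31, Mvk 2.21, Mcm4 2.20, Gins1 2.19, Akr1c6 2.10, Fabp5 2.08, Cyp2r1 1.99 and Stap1 1.98. The downward values were Ppp1r3g -5.82, Pdgfrl -3.58, Igfbp1 -3.25, Tacc2 -2.64, Acot2 -2.52, an immunoglobulin kappa variable gene -2.38, Ccng2 -2.31, Tmc7 -2.30, Ccn2 -2.15 and Pctp -2.05. Of 10 omissions of 1 array, the call was lost in 6 for Akr1c6, 8 for Fabp5 and Ccng2 and 7 for Stap1 and Pctp. It was lost in 9 for the immunoglobulin gene and Tmc7 and in 2 for Cyp2r1. Lgr5, Mcm4 and Gins1 lay at or below the array median on every fasted wild type array, so these sizes are not exact. Mvk lay above it on 1 of 3 fasted wild type arrays. Pdgfrl did on 1 of 3 and the immunoglobulin gene on 2 of 3 fasted knockout arrays. Gene lists also differed by this test, as mean log2 interaction: fatty acid oxidation -0.87, gluconeogenesis -0.43, cholesterol synthesis 0.94, interferon-stimulated genes 0.78, heat shock -0.54, cell cycle 0.77, immediate early genes -0.69, macrophage markers 0.35 and sinusoidal endothelial markers -0.34. With an estimated correlation these 9 calls were lost, with adjusted p between 0.0986 and 0.576. Of 8875 probe sets with no single gene name, which no comparison above uses, 208 were called for fasting in wild type and 18 for knockout against wild type after fasting.

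Clock genes of fasted knockout replicates 1 and 2 lay far from those of replicate 3 and of fasted wild type, as given per array above. A wrong genotype label of replicate 3 is excluded, since its Pml value of 6.14 lies below the lowest wild type array (7.50). The slopes of replicates 1 and 2 on the wild type fasting changes were 0.173 and 0.34 over 2986 genes. That of replicate 3 was 0.405, and the difference between the fed knockout arrays gave 0.071. This argues only weakly against replicates 1 and 2 having been fed, since 1 pair of fed arrays gives no spread. Whether clock phase makes up the 1549 calls between the fasted genotypes cannot be told apart from genotype: 98.1% of the variation of the clock score within groups lies in fasted knockout, and with the score as a covariate the median ratio of new to old log2 change was 0.909 (quartiles 0.74 and 1.05), 34 calls, a median absolute change of 0.55 against 0.61 and a SE of 0.18 against 0.13, with 1 residual degree of freedom fewer. On genes called with replicate 3 and 1 fasted wild type array both left out (895, 907 and 699 genes), that wild type array lay at a median of 0.114, 0.122 and 0.0615 of the way to knockout (upper quartiles 0.323, 0.304 and 0.263), and replicate 3, whose clock genes resemble wild type, at 0.677, 0.676 and 0.655 (lower quartiles 0.418, 0.411 and 0.386); with the wild type arrays kept, replicate 3 lay at 0.664 and replicate 2, whose clock genes lie far from wild type, at 0.690 (quartiles 0.493 and 0.889), and replicate 1 at 1.21; 1 array cannot exclude clock phase. An effect of Pml on the clock, which the design names, remains a candidate explanation that was not tested. So does collection at different times of day, which is not given in the sources used here. Pml was low in fasted knockout replicates 1, 2 and 3 alike (6.05, 6.35 and 6.14). Its loss alone therefore does not separate replicate 3 from replicates 1 and 2.

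Interferon-stimulated genes were higher in fasted knockout (median 0.91 over 39 genes, adjusted p = 5.57e-12), a call lost with an estimated correlation (adjusted p = 0.741). A larger share of macrophages as the whole cause is argued against: the upper quartile of the 18 macrophage markers was 0.496, and 20 of the 39 interferon genes exceeded the highest marker (0.82), with 0 genes shared between the lists; the brightest markers, Vsig4, Slc40a1 and C1qb, differed by 0.30, 0.16 and 0.31. Clock phase cannot be excluded with a score that varies almost wholly inside 1 group. The median was 1.07 with the covariate. Replicate 3, whose clock genes resemble fasted wild type, stood 1.04 above the wild type mean, with 37 of 39 genes above it. Both values rest mainly on replicate 3, so they are not separate evidence. Between the fed genotypes the list did not differ (median 0.02, camera adjusted p = 0.780). With fasting it fell in wild type (median -0.72, 19 of 39 lower) and was not called in knockout (0.19, camera adjusted p = 0.140). The difference thus went with a fall in wild type more than with a rise in knockout. A response to Pml loss remains a candidate explanation, as does a difference in exposure to microbes. Neither was tested against the lack of a difference in fed mice.

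Genes called between knockout and wild type lay near Pml more often than other genes, as linked sequence from the targeted stem cells would give. Averaged over feeding, 3 of 23 called genes other than Pml (13%) lay within 20 Mb of it, against 299 of 13828 others (2.16%; one-sided Fisher exact p = 0.0132): Bco2 (0.96), Colca2 (0.71) and the numbered gene 1700017B05Rik (-0.94), the last named after its value was seen. Within 10 Mb it was 3 of 23 (one-sided Fisher exact p = 0.00316) and within 5 Mb 1 of 23 (0.141); in the fed comparison 2 of 11 genes lay within 20 Mb, Zbtb16 among them (0.0229), 1 within 10 Mb (0.134) and 0 within 5 Mb (1), so the fed p stays under 0.05 at 20 Mb alone; after fasting it was 51 of 1543 (3.31% against 2.04%, one-sided Fisher exact p = 0.00157), with 0.000158 within 10 Mb and 0.0221 within 5 Mb. For fasting in wild type, where no such sequence differs, it was 67 of 2981 (one-sided Fisher exact p = 0.411). Colca2 differed alike in fed and fasted mice (0.78 and 0.65). 1700017B05Rik read -0.22 fed (limma adjusted p = 0.835) and -1.66 fasted. Bco2 read 0.52 fed (limma adjusted p = 0.572) and was called in fasted mice. Zbtb16 read 1.53 fed and -0.28 fasted, and the other gene called in fed mice -1.24 and 0.18. Linked sequence is the same in both states, so position alone does not show that it accounts for the named genes other than Colca2. Of further genes near Pml called after fasting, some differed alike, such as Cryab (-0.43 fed, -0.47 fasted). Others did not, such as Nxpe2 (-0.12 fed, 1.19 fasted). Averaged over feeding, 26.2% of the 302 genes within 20 Mb had an unadjusted limma p under 0.05. It was 15.8% on the rest of the chromosome and 17.1% on other chromosomes. Passenger sequence remains a candidate explanation for genes near Pml, while most of the 1549 genes called after fasting lie elsewhere. An effect of Pml on its neighbours was not tested.

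Other splits of the samples were counted as follows. Of the 10 splits of the 6 fasted arrays, 1 (the real one) called as many as 1549 genes and the highest of the others called 0. For gene lists the real split called 8, 5 splits called as many and the highest other called 15. With 10 splits a share under 0.05 cannot be reached. For knockout against wild type averaged over feeding, 3 of 60 splits called as many as the real 24 genes and 42 of 60 as many as the real 6 lists (highest other 11), so chance cannot be excluded for either count. The highest other gene count was 294, from the split that exchanges the genotype labels in 1 feeding state, which is the interaction and points to a structure of the samples. For fasting averaged over genotype, 1 of 100 splits (the real one) called as many as 3017 genes (highest other 1253). Chance is thus unlikely for that count, though the splits do not tell food removal from clock state. For lists 20 of 100 called as many as the real 9 lists (highest other 11), so chance cannot be excluded there.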

How the results depend on the processing

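Alternatives chosen after the results were seen were the clock covariate, the omission of fasted knockout replicates 1 and 2, single fasted knockout arrays, the exchanged block and the offset. Contrasts are given in the order fasting in wild type, fasting in knockout, fed genotypes, fasted genotypes, interaction, averaged genotype and averaged fasting. Centring (16 results), quantile normalization (9), the mean of probe sets (8) and the offset (9) left each of these counts and levels within 1.5 times or on its side of the threshold. With no filter (22180 genes tested) the counts were 10 for fasting in knockout, 4 fed, 654 fasted, 4 for the interaction and 3 averaged, and the correlation of the fasting responses was 0.22. A stricter filter (9177 genes) gave 452 for fasting in knockout, 501 for the interaction, 97 averaged and a correlation of 0.53; the number of genes tested and adjusted over differs by construction. Trend and robust moderation gave 504, 24, 520 and 97 for fasting in knockout, fed, interaction and averaged genotype, and array weights 37 for the last. The replicate block gave 0 for fasting in knockout and 0 fed by limma (2310 and 1160 genes at an unadjusted p under 0.05), 137 for the interaction, 7 averaged and 1774 for averaged fasting. Same-numbered arrays had correlations of their deviations between -0.17 and 0.11 over 13 pairs. In groups of 2 arrays the deviations mirror each other, and differently numbered pairs were not compared. A pairing by number is therefore neither shown nor excluded. The cause of these changes was not tested beyond that.

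The clock covariate gave 929, 27, 1, 34, 22, 0 (1242 at an unadjusted p under 0.05) and 864 genes in the 7 contrasts, and Pml -1.63 (adjusted p = 0.169, over a range of 0.000619 to 0.173 among 21 alternatives). It takes 1 residual degree of freedom. For the fasted genotypes it rests mainly on fasted knockout replicate 3, as does the omission of replicates 1 and 2, so these are not separate checks. The list means of NRF2 targets (-0.11) and clock genes (-0.18), averaged over feeding, then turned sign and were called. Without fasted knockout replicates 1 and 2 the counts were 2 fed, 6 fasted, 0 for the interaction (2561 at an unadjusted p under 0.05) and 0 averaged (1594), with Pml at -1.64. Of fasted knockout, replicate 1 alone gave 1509 and replicate 2 alone 149 for fasted genotypes. The exchanged block gave 0 fed (1249). The groups of a contrast alone gave 16 for fasting in knockout, 0 fed (1215) and 850 fasted. With an estimated correlation camera called 1, 0, 0, 0, 0, 0 and 1 lists; fry called 12, 7, 0, 2, 3, 1 and 12.

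Leaving out each array in turn gave 1326 to 3062, 1 to 170, 0 to 17, 435 to 1501, 2 to 360, 0 to 257 and 1585 to 3049 genes. It gave 9 to 12, 8 to 11, 6 to 11, 7 to 9, 9 to 11, 4 to 8 and 7 to 10 lists. The correlation was 0.39 to 0.55 and Pml -1.74 to -1.49. Macrophage markers of fed mice turned to 0.16 and were called without fed wild type replicate 1; over the omissions their mean was -0.21 to 0.16. Over these omissions 888 of 980 checks of named genes kept their call for fasting in wild type, 128 of 320 for fasting in knockout, 11 of 90 fed and 548 of 770 for fasted genotypes. It was 142 of 430 for the interaction, 35 of 160 for averaged genotype and 816 of 890 for averaged fasting, with 0 reversed. Of called genes with further probe sets, 24 of 102 for fasting in wild type had 1 of opposite sign. It was 6 of 38 for fasted genotypes, 3 of 8 for the interaction and 26 of 113 for averaged fasting. Signal over background sets a floor: 13942 of 22180 named genes were bright enough to be tested, and nothing is said of the others.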

Other observations

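No test in this part was chosen after its result was seen. After fasting in wild type, of 64 oxidative phosphorylation genes 1 was higher and the median log2 change was 0.01 (adjusted p = 0.402). Of 30 autophagy and lysosome genes 4 were higher and 1 lower (adjusted p = 0.0601), among them Bnip3, a mitophagy receptor (1.14, SE 0.11), and Map1lc3b, the autophagosome protein LC3B (0.71, SE 0.13). Of 25 endoplasmic reticulum stress genes 9 were lower and 3 higher (median -0.36, adjusted p = 0.140). Of 28 NRF2 targets 3 were higher and 4 lower (adjusted p = 0.664). Of 20 antioxidant genes 4 were higher, the metallothioneins Mt1 (4.15) and Mt2 (3.71) among them, and 1 lower. That list has a median of -0.04 and a mean of 0.40, which differ in sign (adjusted p = 0.616). Bile acid genes (1 of 19 higher and 4 lower, adjusted p = 0.149), periportal genes (2 of 17 higher and 4 lower, adjusted p = 0.149) and clock genes (3 of 18 higher and 3 lower, adjusted p = 0.664) were not called. The pericentral list was not called either (3 of 18 lower, adjusted p = 0.421), with a median of 0.08 and a mean of -0.25, which differ in sign.

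For fasting in wild type, macrophage markers had 1 higher and 2 lower of 18 (adjusted p = 0.149), sinusoidal endothelial cells 2 higher of 18 (0.0548), stellate cells 3 higher and 2 lower of 16 (0.180), cholangiocytes 1 higher and 2 lower of 10 (0.520), T and NK cells 0 of 5 (0.664) and adipocytes 0 of 7 (0.845). Between the fasted genotypes, detoxification genes Nqo1 (1.01) and Gstm4 (0.71) were higher in knockout, while the NRF2 target list was not called (3 of 28 higher and 2 lower, adjusted p = 0.861). The pericentral Wnt regulator Rnf43 was higher as well (0.70), and the pericentral list was not called (3 of 18 higher, adjusted p = 0.146). Of 10 omissions of 1 array, the call was lost in 2 for Nqo1, 2 for Gstm4 and 3 for Rnf43.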
